A study of Homo sapiens with 24 samples.

How the data were processed

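RNA of 4 human breast cell lines was sequenced on an Illumina instrument after 16 h with 2 µM withaferin A (WA), a steroidal lactone of the plant Withania somnifera, or with the vehicle dimethyl sulfoxide (DMSO, 0.01%). MCF-10A is an immortalised line of normal mammary epithelium. The others are breast cancer lines, which the labels place in the luminal (MCF-7), HER2-enriched (SK-BR-3) and basal (MDA-MB-231) subtypes. Each of the 8 groups had 3 libraries from replicate dishes, numbered 1 to 3 for DMSO and 4 to 6 for WA, which gave 24 libraries. Replicates were dishes of the same line, so p-values measure the spread between dishes, which may be technical in part, and not between donors.

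Reads were counted per gene with HTSeq 0.6.1 on GRCh37/hg19 and compared with DESeq2, per the submitters' processing notes, which give no DESeq2 version. The aligner, the gene annotation release and the strand setting of the counting are not given in the sources used here. The authors deposited 1 table of FPKM values of 48162 genes and 7 sheets of comparisons. Each sheet held raw gene counts of the libraries compared, deposited as whole numbers. The sheets also held a signal column per library, which the authors made by dividing the counts by DESeq2 size factors. Log2 fold changes, p-values and adjusted p-values of the comparison were deposited in the same sheets and were used here only for the number of genes they call. FPKM values, as deposited, were scaled to gene model length and to the counted reads of the library.

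The sheets did not list every gene. In each of the 7 sheets the genes listed were those with at least 1 read in library 4 or 5 of the group named first, with 0 exceptions. Counts of unlisted genes were therefore recovered from FPKM, gene length and library total. The same calculation gave back 100% of the 571182 deposited counts as the deposited whole number, within a tolerance of 0.0001. Counts of the 29750 genes in at least 1 sheet were used. The remaining 18412 genes were left out, since no sheet gave their length. They took at most 0.00986% of the reads of a library except in MCF-7 DMSO 1, where they took 1.63%. Their highest FPKM was 37.4 in that library and 4.95 in the other libraries. Outside MCF-7 DMSO 1 the libraries held between 13398059 and 23540618 counted reads. After scaling, 1 CPM stood for between 8.16 reads (SK-BR-3 DMSO 3) and 25.6 reads (MDA-MB-231 DMSO 2), so that values under 1 CPM rested on few reads. PCR copies were not marked, so limits from counts cover counting error only.

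Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 18692, and libraries were scaled by the trimmed mean of M-values (TMM). All CPM values in the text are TMM-normalised means ± SD of 3 libraries (n = 3). A quasi-likelihood negative binomial model with robust shrinkage was fitted once to the 24 libraries with 8 group means and 16 residual degrees of freedom, so the groups shared 1 estimate of the spread. Each contrast was tested with edgeR's quasi-likelihood F-test, two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Standard errors of log2 fold changes are the fold change divided by the square root of F. The common biological coefficient of variation was 0.182.

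The contrasts were the WA response of each line, the response of each cancer line minus that of MCF-10A (the interaction), the mean of the 3 cancer responses minus that of MCF-10A (the mean interaction), and each WA-treated cancer line against WA-treated MCF-10A. A gene belonged to the cancer-selective response when it was called with 1 sign in all 3 cancer lines and its mean interaction was called with the same sign. DMSO-treated lines were compared in the same fit as the background of the comparisons between WA-treated lines. The contrasts, the gene lists and the rule for the genes named were fixed before the data were examined. The rule took, per response, the 8 highest and the 8 lowest called protein-coding genes with a mean of at least 5 CPM in 1 of the 2 groups and no overlap between the WA and DMSO values. It also took the 4 members with the smallest p of each gene list described, the 8 highest and 8 lowest mean interactions of the cancer-selective response, the 4 highest and 4 lowest genes of each comparison of WA-treated lines, and a short set of markers and stress genes fixed by name. Genes that mark sex are not reported. Other genes are named only where it is said that they were chosen after their values were seen.

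There were 33 gene lists: heat shock, NRF2 antioxidant response, unfolded protein response of the endoplasmic reticulum, integrated stress response, proteasome, autophagy and lysosome, p53 targets, G2/M, DNA replication, homologous recombination and Fanconi anaemia repair, apoptosis regulators, NF-kB targets, interferon-stimulated genes, oestrogen receptor targets, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, tubulins, metallothioneins, epithelial to mesenchymal transition, YAP and TEAD targets, Notch, immediate early genes, histones, cytosolic ribosomal proteins, luminal markers, basal markers, the HER2 amplicon, fibroblast markers and leukocyte markers. Each list was tested against all other genes with camera of limma 3.58.1 in the 4 responses and the mean interaction, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over all lists and contrasts together. Camera was run again with the correlation estimated from the data. Where this ended a call, the second adjusted p is given beside the list. Numbers of called members were also computed with p-values adjusted over the list alone.

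The alternatives planned were DESeq2 1.42.0 as the test, DESeq2 size factors as the scaling, no filter on low counts other than 1 count, a fit of only the groups compared, no fold threshold, the library number as a block between lines, each library left out in turn, and the estimated correlation for the lists. Alternatives written for normalized values only (other pseudocounts, a filter on FPKM, quantile normalization) did not apply, since the sheets held counts. A further 3 were added after the data were seen: limma voom with library quality weights, a fit without mitochondrially encoded genes, and the estimated correlation with each library left out. The analysis was tested on simulated counts made from the DMSO group means, depths and dispersions of these libraries, with 200 changed genes. Each gene had 1 dispersion for all 8 groups, whereas the real groups differed (biological coefficient of variation 0.0472 in MDA-MB-231 DMSO and 0.710 in MCF-7 DMSO). The shares and false calls below therefore do not cover errors from unequal spread or from a library such as MCF-7 DMSO 1. For the MCF-7 response, over 18294 genes, 32.5% of the genes changed by 1 on the log2 scale, 77.5% of those changed by 1.5, 82.5% of those changed by 2 and 90% of those changed by 3 were called, with 3 false calls. For MCF-10A the shares were 30%, 70%, 65% and 95% with 2 false calls. For the mean interaction they were 20%, 70%, 80% and 60% with 1 false call. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.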

Results

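The study asked how 4 human breast lines respond to withaferin A (WA), and which changes are shared by cancer lines of different subtypes or set them apart from a normal line. Each line (normal MCF-10A, luminal MCF-7, HER2-enriched SK-BR-3, basal MDA-MB-231) gave 3 DMSO and 3 WA libraries after 16 h. Counted reads ranged from 13398059 to 23540618 in 23 libraries and were 6692750 in MCF-7 DMSO 1. That library also differed in the number of genes with a value above 0, which was 44170 against 18055 to 21885 elsewhere. Of its reads, 1.63% lay in genes that no comparison sheet listed, against at most 0.00986% in any other library. Reads in mitochondrially encoded genes were the other large difference. Their share was 31.5%, 13.6% and 33.0% in the SK-BR-3 DMSO libraries and 10.7% to 12.9% in the SK-BR-3 WA libraries. It was 10.5% to 11.3% against 5.41% to 6.24% in MCF-7, 4.62% to 5.62% against 2.63% to 3.33% in MDA-MB-231, and 3.09% to 4.69% against 2.79% to 3.60% in MCF-10A (DMSO against WA).

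**Figure D1:**
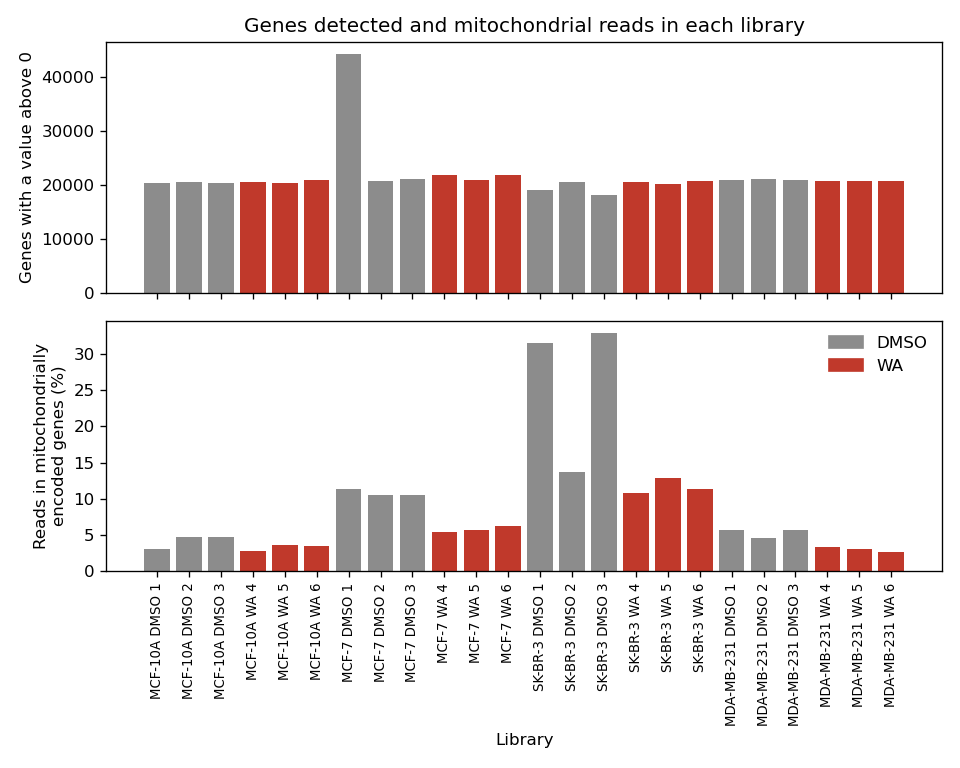
Genes with a value above 0 (number, upper panel) and reads in mitochondrially encoded genes (% of counted reads, lower panel) in each of the 24 libraries, bars coloured by treatment. MCF-7 DMSO 1 has 44170 genes above 0 against at most 21885 in the others, and SK-BR-3 DMSO 1 and 3 have mitochondrial shares of 31.5% and 33.0%.

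Replicates resembled each other closely in most groups. The biological coefficient of variation was 0.710 in MCF-7 DMSO, 0.271 in SK-BR-3 DMSO and 0.0472 to 0.128 in the other 6 groups. No pair of replicates differed by as little as sampling noise (chi-square per degree of freedom from 2.78 to 138), so each library counted once. The known markers of the lines were in place. ERBB2, the gene of the HER2 receptor (chromosome 17, 37844167 to 37886679), stood at 4742 ± 116 CPM (SD, n = 3) in SK-BR-3 DMSO and at 102 to 151 CPM in the other lines. Its neighbour GRB7 stood at 675 ± 51.2 CPM in SK-BR-3. ESR1, the oestrogen receptor, was at 129 ± 17.1 CPM in MCF-7 DMSO and at most 1.78 CPM in the other lines. GATA3, a luminal transcription factor, reached 1293 ± 240 CPM in MCF-7. The mesenchymal filament gene VIM reached 599 ± 14 CPM in MDA-MB-231. The basal genes KRT5 (9017 ± 860 CPM) and TP63 (204 ± 10.7 CPM) marked MCF-10A.

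In MCF-10A, the normal line, WA was followed by an antioxidant response and by lower expression of cell-cycle, NF-kB and Notch genes, while HSPA1A and DDIT3 were not called. HMOX1, the gene of haem oxygenase 1 (chromosome 22, 35776354 to 35790207), rose from 12.7 ± 1.51 to 515 ± 53.8 CPM (log2 fold change 5.35, SE 0.14, adjusted p = 2.31e-18). The small heat shock protein gene CRYAB rose from 45.4 ± 11.7 to 315 ± 63.2 CPM. AURKB, a mitotic kinase, fell from 5.10 ± 0.38 to 0.57 ± 0.11 CPM, and TNFAIP3, an inhibitor and target of NF-kB, fell from 76.8 ± 1.47 to 7.67 ± 0.82 CPM. In all, 1010 of 18692 genes were called by edgeR's quasi-likelihood test, 318 higher and 692 lower.

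Besides HMOX1 and CRYAB, the 8 highest fold changes in MCF-10A were those of TAS1R3, FLJ27365, C1orf132, F2RL2, SLCO4A1 and AC132872.2, with log2 fold changes of 2.21 to 3.18. Among the 8 lowest, IGFN1 fell from 113 ± 9.31 to 5.74 ± 1.10 CPM, SERPINB2 from 26.1 ± 3.26 to 1.3 ± 0.48 CPM and ZNF750, an epidermal transcription factor, from 21.2 ± 1.66 to 1.11 ± 0.25 CPM. GJA1, the gap junction gene connexin 43, and CYP1A1, a target of the aryl hydrocarbon receptor, fell by 4.23 and 4.13 on the log2 scale. PPP2R2B and EPHA5 also fell. The desmosomal cadherin gene DSG4 was at 5.74 ± 0.70 CPM in DMSO and 0.04 CPM (3 counts in all) in WA. Some of these calls rested on every library. Those of F2RL2, EPHA5 and DSG4 were lost without any 1 of the 6 MCF-10A libraries (adjusted p up to 0.0944, 0.153 and 0.112), that of C1orf132 without any of them except WA 5 (up to 0.0936), and that of PPP2R2B without WA 5 or WA 6 (up to 0.0651).

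Of 27 NRF2 antioxidant genes, 9 rose and 0 fell in MCF-10A (camera adjusted p = 4.96e-43). Next to HMOX1, these included TRIM16L (log2 1.98), OSGIN1 (2.04) and the haem transporter gene SLC48A1 (1.73). The autophagy receptor gene SQSTM1 rose from 759 ± 16 to 2647 ± 83.8 CPM, while the autophagy and lysosome list had a single call (adjusted p = 0.24). Of 25 heat shock genes, 5 rose and 1 fell, with a list median of 0.04 (adjusted p = 0.573). Among them were HSP90AA1 (log2 1.25), DNAJB4 (1.37) and, lower, HSPA4L (-1.44), whereas HSPA1A stood at 111 ± 7.89 and 114 ± 9.87 CPM. In the integrated stress response list, 3 of 25 genes rose and 2 fell (adjusted p = 0.978), the latter being the amino acid transporter gene SLC7A5 (log2 -1.56) and the transcription factor gene ATF3 (-2.33). DDIT3, which encodes CHOP, was at 4.30 ± 0.70 and 3.29 ± 0.24 CPM. The unfolded protein response list (20 genes, median 0.09) had 0 calls by edgeR or DESeq2, 5 genes at an unadjusted p under 0.05 and a camera adjusted p of 0.0315, with adjusted p = 0.635 with an estimated correlation and 0.0503 without MCF-10A WA 5. Its smallest p-values were those of HSPA5, HERPUD1, HSP90B1 and SYVN1, with log2 fold changes of 0.54 to 0.61. The 32 proteasome genes had 0 calls by edgeR or DESeq2, 17 at an unadjusted p under 0.05 and a median of 0.27 (adjusted p = 1.18e-05, and adjusted p = 0.478 with an estimated correlation).

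Proliferation genes were lower in MCF-10A. Of 27 G2/M genes, 21 fell (median -1.59, adjusted p = 4.84e-47), such as TOP2A, from 39.7 ± 4.41 to 8.69 ± 0.98 CPM, CCNA2 (log2 -2.19) and CDC20 (-2.35). Of 30 DNA replication genes, 17 fell (median -1.05, adjusted p = 1.26e-34), among them RRM2, from 91.3 ± 3.17 to 12 ± 1.51 CPM, CDC6 (-1.48) and MCM10 (-1.92). Of 22 genes of homologous recombination and Fanconi anaemia repair, 10 fell (median -0.91, adjusted p = 1.88e-20), with FANCD2 at -2.10 and EXO1 at -2.01. Of 21 p53 targets, 4 fell, among them GADD45A, BTG2 and DDB2 (median -0.30, adjusted p = 0.000228). GADD45A, a growth arrest gene, went from 115 ± 19.2 to 30.3 ± 5.89 CPM. Against the other genes, 14 replication-dependent histone genes were higher (median 0.66, adjusted p = 0.000193), with 3 calls that included HIST1H2AC and HIST1H4H. With an estimated correlation the p53 list passed with all libraries but not without any 1 of 6 (adjusted p up to 0.227), and the histone list not without any 1 of 4 (up to 0.0945).

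NF-kB targets, Notch genes and basal keratinocyte genes were also lower in MCF-10A. Of 19 NF-kB targets, 9 fell, or 12 with p-values adjusted over the list alone (median -1.33, adjusted p = 7.16e-16), such as RELB (log2 -1.91) and NFKBIA (-1.62). Of 16 Notch genes, 3 fell (adjusted p = 1.63e-06): the Notch target NRARP, from 20.7 ± 1.24 to 1.53 ± 0.44 CPM, NOTCH1 (-1.36) and NOTCH3 (-1.85). Of 16 basal markers, 8 fell, including KRT6B (-2.16), CDH3 (-1.28) and KRT5 (-1.83, adjusted p = 0.00121). The basal list had an adjusted p of 0.000175, and adjusted p = 0.159 with an estimated correlation, or 0.00106 and 0.0318 with that estimate without MCF-7 DMSO 1 or 3. For the luminal markers (1 rose, 4 fell of 15) these values were 0.00519 and adjusted p = 0.235 with an estimated correlation, and 0.0566 without MCF-7 DMSO 1, which shares the estimate of the spread. ELF3 stood at -3.15 and KRT18 at 1.2. Among 21 interferon-stimulated genes, 4 fell, including OAS3 (-1.83), with 0.0205 and adjusted p = 0.143 with an estimated correlation. Oestrogen receptor targets (3 of 20 fell) had 0.0235 and adjusted p = 0.261 with an estimated correlation, and 0.0612 without MCF-7 DMSO 1. Fatty acid synthesis genes (0 of 15 called by edgeR or DESeq2, 13 at an unadjusted p under 0.05, median 0.39) had 0.00704 and adjusted p = 0.224 with an estimated correlation, or 0.0439 with that estimate without MCF-7 DMSO 1. Tubulins (1 of 19 fell, TUBA1A at -1.39) had 0.000338 and adjusted p = 0.23 with an estimated correlation, or 0.0489 with that estimate without MCF-10A DMSO 1. The immediate early list had 2 higher and 3 lower genes of 21 (adjusted p = 0.164), with FOSB at -1.62. The epithelial to mesenchymal list had 4 of 23 lower (adjusted p = 0.0864), including COL1A1 (-1.66), FN1 (-1.08) and the E-cadherin gene CDH1 (-1.40). Nuclear oxidative phosphorylation (0.354), mitochondrially encoded genes (0 of 13 called by edgeR or DESeq2, 6 at an unadjusted p under 0.05, median -0.53, 0.142), cholesterol synthesis (0.41) and apoptosis (0.241) did not pass. Without MCF-10A DMSO 1 the adjusted p was 0.0317 for immediate early genes, 0.0334 for the epithelial to mesenchymal list, 0.0333 for oxidative phosphorylation and 0.0123 for mitochondrially encoded genes. The last passed also without MCF-10A WA 5 (0.0436) or SK-BR-3 DMSO 2 (0.0071), the immediate early list without SK-BR-3 DMSO 2 (0.0349) and the epithelial to mesenchymal list without MDA-MB-231 WA 5 (0.0293). None of these 4 lists passed without those libraries when the correlation was estimated (0.661 or more). Counts that moved by over 1.5 times without 1 library in MCF-10A included those of basal markers (5 to 8 lower), heat shock genes (3 to 5 higher and 1 to 2 lower), immediate early genes (1 to 2 and 3 to 5) and fatty acid synthesis genes (up to 1 higher).

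In MCF-7, the luminal line, WA was followed by heat shock, antioxidant and integrated stress responses together, and by lower expression of ESR1 and of interferon-stimulated genes. HMOX1 rose from 19.7 ± 2.22 to 2239 ± 264 CPM (log2 fold change 6.82, SE 0.15, adjusted p = 3.1e-20). HSPA1A, the inducible HSP70 gene (chromosome 6, 31783291 to 31785717), rose from 115 ± 27.1 to 1827 ± 185 CPM (3.99, SE 0.16, adjusted p = 3.84e-15). CHAC1, a glutathione-degrading enzyme gene induced through ATF4, rose from 2.46 ± 0.35 to 87.7 ± 13.9 CPM. ESR1 fell from 129 ± 17.1 to 38.4 ± 2.33 CPM (-1.75, SE 0.22, adjusted p = 8.88e-07). The edgeR test called 3730 genes, 897 higher and 2833 lower, and the median log2 fold change of all genes was -0.21. MCF-7 DMSO 1, the library with 44170 genes above 0, shaped the lower side of this count. Without it, 2972 genes were called, 1536 higher and 1436 lower, and 816 of the 897 higher but 1279 of the 2833 lower genes were called again.

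**Figure D2:**
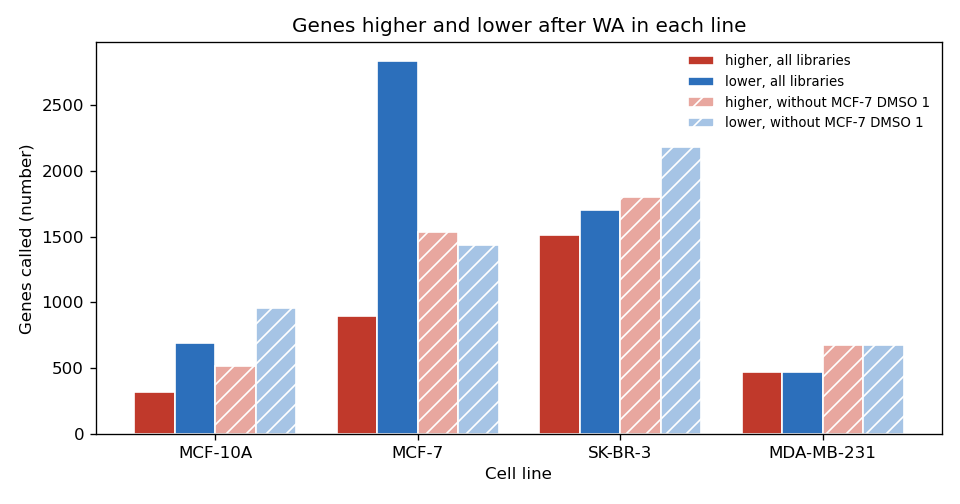
Number of genes called higher or lower after WA in each line by edgeR's quasi-likelihood test, with all 24 libraries (plain bars) and without MCF-7 DMSO 1 (hatched bars). In MCF-7 the lower calls go from 2833 to 1436 and the higher calls from 897 to 1536 when that library is left out.

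The highest fold changes in MCF-7 beside HMOX1 and CHAC1 were those of HSPA6, an HSP70 gene silent without stress (0.87 ± 0.39 to 90.3 ± 40.1 CPM, log2 6.82), and FOSL1, an AP-1 subunit gene (1.92 ± 0.47 to 86.1 ± 7.22 CPM, 5.54). KRT16, TEX19, PTPRH and ULBP1 followed at 4.19 to 4.57. Among the 8 lowest, AFAP1L2 fell from 22.8 ± 1.71 to 0.68 ± 0.27 CPM and SLITRK6 from 5.08 ± 1.36 to 0.16 ± 0.04 CPM. ARMCX4 and ANKRD35 fell by 5.36 and 5.15 on the log2 scale, and FOXI1 was at 5.18 ± 0.52 CPM in DMSO and 0.06 CPM (3 counts) in WA. LRP2, SOX6 and FBN1, the remaining ones, rested on MCF-7 DMSO 1, where they stood at 22.2, 14.9 and 17.2 CPM against means of 1.51, 0.43 and 1.13 CPM in MCF-7 DMSO 2 and 3. Their log2 fold changes went from -6.64, -5.65 and -4.99 to -4.20, -2.16 and -2.86 without it.

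The heat shock, NRF2 and integrated stress response lists were each higher in MCF-7. Of 25 heat shock genes, 19 rose and 0 fell (median 1.51, adjusted p = 4.15e-38), including the co-chaperone genes DNAJB1, from 199 ± 39.3 to 1236 ± 223 CPM, and HSPH1 (log2 2.36), and BAG3 (1.99). Of 27 NRF2 genes, 17 rose (median 1.75, adjusted p = 7.94e-56), with OSGIN1 at 3.73 and MAFG at 2.48. Of 25 integrated stress response genes, 20 rose (median 2.04, adjusted p = 1.58e-52), among them SESN2 (3.44), TRIB3 (2.77) and SLC3A2 (2.92). DDIT3 rose from 2.67 ± 1.19 to 34.2 ± 5.47 CPM. The unfolded protein response list did not pass (1 of 20 rose, DNAJB9 at 1.05, adjusted p = 0.28), but did without MCF-7 DMSO 3 (0.0469, and 0.745 with an estimated correlation). Of 20 autophagy and lysosome genes, 4 rose (adjusted p = 2.1e-07), including SQSTM1, MAP1LC3B and GABARAPL1. Of 21 p53 targets, 6 rose (median 0.64, adjusted p = 1.43e-05), such as GADD45A, from 9.95 ± 2.91 to 85.0 ± 19.7 CPM, PLK3 (2.09), AEN (1.62) and CDKN1A (1.43). Of 21 immediate early genes, 8 rose (median 0.95, adjusted p = 6.15e-11, and adjusted p = 0.141 with an estimated correlation, or 0.0434 with that estimate without SK-BR-3 DMSO 2), with DUSP5 at 2.77. For the proteasome list (1 of 32 rose) the values were 0.0109 and adjusted p = 0.764 with an estimated correlation. The apoptosis list had 5 higher and 3 lower genes of 24 (0.0442, and adjusted p = 0.402 with an estimated correlation). Neither passed without MCF-7 DMSO 1 (0.203 and 0.107). The death receptor gene TNFRSF10B rose (2.05), as did PMAIP1 (1.55) and MCL1 (1.08), while BMF (-2.43) and BCL2 (-2.16) fell. MCL1 stood at 0.99 without MCF-7 DMSO 1 and DNAJB9 at 0.98 without MCF-7 WA 4, both under the fold threshold.

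Lower groups in MCF-7 included the interferon-stimulated genes, of which 13 of 21 fell (median -1.53, adjusted p = 3.37e-11). OAS3 fell from 220 ± 37.6 to 26.7 ± 6.33 CPM and IFIT1 from 50.1 ± 4.68 to 3.65 ± 0.98 CPM. Of 20 oestrogen receptor targets, 10 fell and 1 rose (median -0.93, adjusted p = 0.000349, and adjusted p = 0.0619 with an estimated correlation, or 0.00118 with that estimate without MCF-7 DMSO 1). GREB1 fell from 368 ± 45.2 to 100 ± 18.9 CPM, STC2 rose (1.99). CA12 and RARA fell by 1.07 and 1.14 on the log2 scale, but were at -0.98 and -0.93, not called, without MCF-7 DMSO 3. Cell-cycle lists were lower: 13 of 27 G2/M genes fell (median -0.98, adjusted p = 5.51e-16), 10 of 30 DNA replication genes (adjusted p = 1.87e-14) and 8 of 22 repair genes (adjusted p = 2.88e-05), with TOP2A at -2.00, GINS1 at -1.56 and FANCI at -1.16. With an estimated correlation these 3 lists passed with all libraries, but without 1 library the adjusted p reached 0.154, 0.244 and 0.306, and 0.1 and 0.0815 for autophagy and p53. Of 13 mitochondrially encoded genes, 9 fell (median -1.22, adjusted p = 0.00485, and adjusted p = 0.728 with an estimated correlation). MT-CO3 went from 4878 ± 129 to 1658 ± 117 CPM. NF-kB targets had 2 higher and 11 lower genes of 19 (median -1.73, adjusted p = 0.172), or 2 and 7 without MCF-7 DMSO 1, and an adjusted p of 0.0388 without MCF-7 DMSO 2 (0.426 with an estimated correlation). The tubulin gene TUBA4A rose (2.59), while TUBB fell (-1.03, or -0.86, not called, without MCF-7 DMSO 3, and likewise without MCF-7 DMSO 2 or WA 4). Lists that did not pass were cholesterol synthesis (0.0817, but 0.0289 without MCF-7 DMSO 2 and 0.0141 without MCF-7 DMSO 3), fatty acid synthesis (3 rose and 1 fell of 15, 0.191, but 0.0489 without MCF-7 DMSO 2), luminal markers (0.241, but 0.0221 without MCF-7 DMSO 1), nuclear oxidative phosphorylation (0.171, but 0.00574 without MCF-7 DMSO 1) and histones (0.507). None of these passed without those libraries when the correlation was estimated, with 0.116 for luminal markers, 0.604 for oxidative phosphorylation, 0.362 for fatty acid synthesis, and 0.426 and 0.547 for cholesterol synthesis. Without 1 library, from 8 to 17 G2/M genes, 5 to 9 repair genes and 7 to 12 NF-kB targets were lower in MCF-7, and from 7 to 13 immediate early genes, 0 to 2 unfolded protein response genes and 0 to 1 proteasome genes were higher.

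Markers of other cell types moved with MCF-7 DMSO 1. Of 7 fibroblast markers tested, 4 were lower and 1 higher (median -3.33, adjusted p = 0.978), and of 6 leukocyte markers 3 were lower (median -2.52, adjusted p = 0.579). Without MCF-7 DMSO 1 the medians were 0.58 and 0.48. The metallothionein median was -2.35 with that library and 0 without it. For the epithelial to mesenchymal list the calls were 4 higher and 6 lower with it and 6 and 3 without, and for the YAP and TEAD targets 3 and 6 against 5 and 4. Over all left-out libraries, lower members ranged from 1 to 5 for the fibroblast markers, 1 to 4 for the leukocyte markers, 2 to 8 for the epithelial to mesenchymal list and 4 to 7 for the YAP and TEAD targets. For NOTCH4 the log2 fold change was -3.67 with it and -1.69, no longer called (adjusted p = 0.076), without it.

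In SK-BR-3, the HER2-enriched line, HMOX1, HSPA1A and HSPA6 reached the highest mean CPM of the 8 groups after WA, and immediate early genes were called in both directions. HSPA6 rose from 0.84 ± 0.13 to 307 ± 29.1 CPM (log2 fold change 8.53, SE 0.33, adjusted p = 9.72e-15), FOSL1 from 0.54 ± 0.14 to 187 ± 14.1 CPM (8.43) and HMOX1 from 24 ± 3.24 to 4217 ± 152 CPM (7.45, SE 0.15, adjusted p = 7.52e-21). HSPA1A rose from 176 ± 32.2 to 4205 ± 397 CPM (4.58). FOSB, another AP-1 gene, fell from 630 ± 245 to 43.4 ± 10.4 CPM and the chemokine gene CCL2 from 17.4 ± 6.39 to 0.72 ± 0.46 CPM. The edgeR test called 3210 genes, 1509 higher and 1701 lower.

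Others among the 8 highest in SK-BR-3 were ARC (6.84), the cystine transporter gene SLC7A11, from 1.28 ± 0.29 to 75.6 ± 10.0 CPM, and GZMM (5.11). CYP4F11 and ASGR1 reached 7.02 ± 1.98 and 5.54 ± 2.87 CPM from 3 counts each in DMSO. The 8 lowest held C8orf4 (-5.14), HOXC4 (-4.78), the urokinase gene PLAU, from 15.1 ± 8.26 to 0.68 ± 0.62 CPM, RBBP8NL, from 75.2 ± 9.65 to 4 ± 0.67 CPM, ARHGAP24 (-4.10) and OSBPL7 (-3.77). Of 25 heat shock genes, 21 rose (median 1.93, adjusted p = 4.62e-46), such as HSPB8 (4.90), BAG3, from 87.1 ± 8.71 to 750 ± 17.5 CPM, and DNAJA1 (2.22). In the NRF2 list 13 of 27 rose and 1 fell (median 0.97, adjusted p = 5.43e-30), with TXNRD1 going from 190 ± 18.3 to 1259 ± 88.7 CPM. Of 25 integrated stress response genes, 16 rose (median 1.75, adjusted p = 1.52e-23), including CHAC1 (4.96), SESN2 (3.57), PSAT1 (2.56), ASNS (2.52) and DDIT3 (2.57). Of 20 autophagy and lysosome genes, 6 rose (median 0.72, adjusted p = 1.02e-10), with ULK1 at 1.56 and GABARAPL1 at 3.18. The unfolded protein response list had 1 higher and 1 lower gene (adjusted p = 0.417), the higher one being DNAJC3, at 0.96 and 0.99, not called, without SK-BR-3 DMSO 2 or WA 4. Of 32 proteasome genes, 3 rose, including PSMD12 (1.35), with a list adjusted p of 3.07e-05, and adjusted p = 0.519 with an estimated correlation. Among p53 targets, 2 rose and 1 fell (adjusted p = 0.471), and CDKN1A, the cell-cycle inhibitor p21, went from 21.5 ± 6.47 to 139 ± 3.89 CPM.

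Of 30 DNA replication genes, 19 fell in SK-BR-3 (median -1.23, adjusted p = 3.83e-17), among them E2F1, from 60.3 ± 14.7 to 12.8 ± 0.78 CPM, POLA1 (-1.88) and RRM2 (-1.60). Of 22 repair genes, 7 fell (adjusted p = 3.17e-05), with FANCG at -1.54. Both lists passed with an estimated correlation and all libraries, but not without any 1 of 5 (adjusted p up to 0.0996 and 0.19), nor did autophagy without any 1 of 3 (up to 0.0802). In the G2/M list 2 of 27 fell, KIF20A (-1.09) and CDK1 (-1.25, or -0.95, not called, without SK-BR-3 DMSO 2), with 0.00042 and adjusted p = 0.379 with an estimated correlation. NF-kB targets had 10 of 19 lower (12 adjusted over the list alone, median -1.90, adjusted p = 0.00024, and adjusted p = 0.184 with an estimated correlation), with TNFAIP3 falling from 24.5 ± 8.15 to 1.92 ± 0.49 CPM. The immediate early list had 3 higher and 7 lower genes of 21 (adjusted p = 0.0864), the latter including JUN (-2.23) and KLF4 (-2.56). This list passed without SK-BR-3 DMSO 1 (0.00345) or 3 (0.00653), and without MCF-7 DMSO 1 (0.0426) or 3 (0.0321), but in none of these fits with an estimated correlation (0.697 to 0.761, and 0.723 without MCF-7 DMSO 1). The Notch target HES1 fell from 531 ± 203 to 98.2 ± 6.1 CPM, in a list with 3 of 16 lower (adjusted p = 0.241), or 5 without MCF-7 DMSO 1. Of 24 cholesterol synthesis genes 5 rose (0.00114, and adjusted p = 0.186 with an estimated correlation, or 0.0148 with that estimate without MCF-7 DMSO 1), including HMGCS1 (1.81) and MSMO1 (1.19). SREBF1 (-1.38) and FASN, the fatty acid synthase gene, fell, the latter from 4358 ± 249 to 2160 ± 86.6 CPM, while ME1 (2.03) and ELOVL5 (1.48) rose. The log2 fold change of FASN was -1.01, and -0.97 and -0.98, not called, without SK-BR-3 DMSO 3 or WA 4. Fatty acid synthesis as a list had 2 higher and 4 lower genes (adjusted p = 0.781). Oestrogen receptor targets (0.893), histones (0.936) and interferon-stimulated genes (2 rose and 3 fell of 21, 0.241) did not pass either.

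Of 13 mitochondrially encoded genes, 8 fell in SK-BR-3 (median -1.83, adjusted p = 0.000147, and adjusted p = 0.539 with an estimated correlation, or 0.0289 with that estimate without SK-BR-3 DMSO 2), in a line whose DMSO libraries held 31.5%, 13.6% and 33.0% mitochondrial reads. MT-CO1 stood at 105028 ± 55326 CPM in DMSO and 21577 ± 2272 CPM in WA. Nuclear genes of oxidative phosphorylation had 4 of 29 lower (median -0.44, adjusted p = 0.00171, and adjusted p = 0.684 with an estimated correlation), such as NDUFS3 (-1.36). Luminal markers had 2 of 15 lower, MUC1 (-2.13) and SPDEF (-1.37), with 0.019 and adjusted p = 0.353 with an estimated correlation. TUBB fell from 2134 ± 163 to 700 ± 20.7 CPM. In the HER2 amplicon 1 of 10 genes fell, PGAP3 (-1.05, or -0.96, not called, without SK-BR-3 DMSO 2). ERBB2 was at 4742 ± 116 and 3276 ± 159 CPM (-0.53, adjusted p = 3.35e-05), under the fold threshold. Other counts that moved by over 1.5 times without 1 library in SK-BR-3 included those of mitochondrially encoded genes (8 to 13 lower), cholesterol synthesis (3 to 8 higher), the unfolded protein response (0 to 2 higher), oxidative phosphorylation (2 to 5 lower), luminal markers (2 to 4), G2/M (1 to 4), fatty acid synthesis (2 to 4), p53 targets (1 to 2) and the HER2 amplicon (0 to 1).

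In MDA-MB-231, the basal line, antioxidant genes, HSPA6 and HSPA1A rose, together with histone genes. HMOX1 rose from 8.41 ± 0.68 to 1221 ± 43.4 CPM (log2 fold change 7.18, SE 0.15, adjusted p = 1.58e-20), HSPA6 from 0.77 ± 0.22 to 56.5 ± 2.31 CPM (6.19) and HSPA1A from 20.2 ± 1.02 to 450 ± 34.4 CPM (4.48, SE 0.17, adjusted p = 1.55e-15). ADM, the adrenomedullin gene, rose from 29.2 ± 1.14 to 454 ± 5.26 CPM. The clock gene PER2 fell from 11.2 ± 1.05 to 1.44 ± 0.29 CPM, and KIAA1199, a gene involved in hyaluronan breakdown, from 179 ± 1.61 to 28.0 ± 1.37 CPM. The edgeR test called 948 genes, 473 higher and 475 lower.

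COL20A1, TNFSF9, ZFAND2A and OSGIN1 completed the 8 highest in MDA-MB-231, at log2 3.22 to 3.93. ELFN2, FOXO6, TNS4, GPR110, GBP4 and PPL completed the 8 lowest, at -2.74 to -2.60, the call of GBP4 being lost without any 1 of the MDA-MB-231 libraries except WA 6 (adjusted p up to 0.123). Of 27 NRF2 genes, 15 rose (median 1.22, adjusted p = 8.89e-68), with TXNRD1 going from 527 ± 13.8 to 2292 ± 65 CPM. Of 25 heat shock genes, 11 rose (median 0.99, adjusted p = 3.45e-38), including HSPB8 (2.80) and DNAJB1, from 236 ± 3.18 to 810 ± 58.7 CPM. Of 25 integrated stress response genes, 7 rose (median 0.44, adjusted p = 9.6e-06, and adjusted p = 0.195 with an estimated correlation), with CHAC1 at 1.81, SESN2 at 1.54 and DDIT3 at 1.94. The unfolded protein response list had 0 calls of 20 by edgeR or DESeq2, with 8 genes at an unadjusted p under 0.05 (list adjusted p = 0.4). Of 20 autophagy and lysosome genes, 3 rose, SQSTM1 (2.10), GABARAPL1 (2.23) and MAP1LC3B (1.10), with 0.00433 and adjusted p = 0.165 with an estimated correlation. The p53 list had 2 higher genes, GADD45A, from 42.1 ± 2.51 to 116 ± 7.26 CPM, and AEN, and 1 lower, DDB2 (adjusted p = 0.471). Immediate early genes had 4 higher, such as DUSP1 (2.07) and EGR1, from 95.8 ± 9.3 to 335 ± 15 CPM, and 1 lower of 21 (0.000173, and adjusted p = 0.48 with an estimated correlation). Of 14 histone genes, 6 rose (median 0.90, adjusted p = 1.75e-07), including HIST1H4H (1.85) and HIST1H2BD (1.78).

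DNA replication genes were lower in MDA-MB-231 (4 of 30 fell, median -0.65, adjusted p = 4.77e-15), with MCM6 at -1.11 and MCM3 at -1.15. The list passed with an estimated correlation and all libraries, but not without any 1 of 5 (adjusted p up to 0.129). In the G2/M list 2 of 27 fell, TOP2A (-1.16) and KIF20A (-1.03, or -0.97 and -0.98, not called, without MDA-MB-231 DMSO 2 or WA 5), with 0.000583 and adjusted p = 0.402 with an estimated correlation. In the repair list 2 of 22 fell, including FANCD2 (-1.25), with 0.0082 and adjusted p = 0.195 with an estimated correlation. NF-kB targets had 6 of 19 lower, such as BCL3 (-1.70) and ICAM1 (-1.47), with 0.000123 and adjusted p = 0.143 with an estimated correlation. Interferon-stimulated genes had 2 of 21 lower, OAS3 (-1.69) and IFIH1 (-1.21), at an adjusted p of 0.00145, a list that passed with an estimated correlation but not without any 1 of 9 libraries (up to 0.152). PLAU fell from 149 ± 2.85 to 42.0 ± 4.54 CPM. Of 13 mitochondrially encoded genes, 6 fell (median -0.97, adjusted p = 0.00165, and adjusted p = 0.674 with an estimated correlation). The call of MT-ND4 among them was lost without any 1 of 15 libraries, at log2 fold changes less than 1 in size, and 5 fell without MCF-7 DMSO 1, with a range of 2 to 7 over all left-out libraries. The G2/M and repair counts ranged from 1 to 2. Cholesterol synthesis genes had 1 call of 24 (median 0.25, adjusted p = 0.00171, and adjusted p = 0.203 with an estimated correlation, or 0.0278 with that estimate without MCF-7 DMSO 1). BMF, a pro-apoptotic gene, fell (-3.17) in an apoptosis list with 2 of 24 lower (adjusted p = 0.957). HES1 fell (-2.19). Oestrogen receptor targets (0.933), fatty acid synthesis (0.75), nuclear oxidative phosphorylation (0.241), luminal markers (0.24) and the proteasome (0.191) did not pass.

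**Figure D3:**
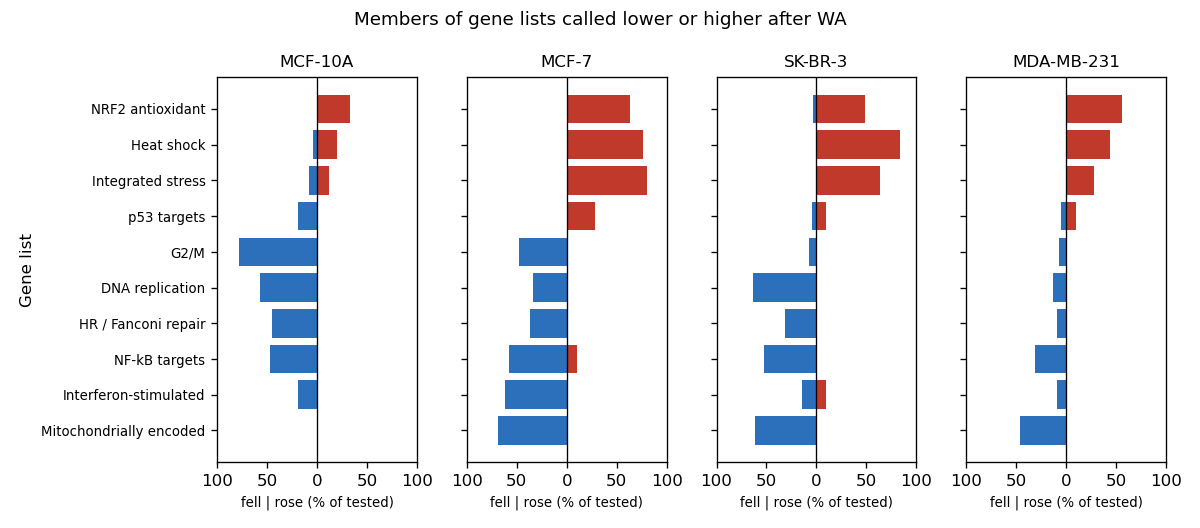
Share of the tested members of 10 gene lists that were called higher (red, to the right) or lower (blue, to the left) after WA in each line, in % of tested members. Heat shock genes had 19, 21 and 11 of 25 members higher in the luminal, HER2-enriched and basal line and 5 in MCF-10A, where G2/M genes had 21 of 27 lower.

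Other lists had no calls or did not pass. The 37 cytosolic ribosomal protein genes and the 19 glycolysis genes had 0 calls by edgeR or DESeq2 in all 4 lines (adjusted p of 0.691 to 0.978 and of 0.24 to 0.957). At an unadjusted p under 0.05 there were 1, 0, 4 and 0 ribosomal and 9, 9, 10 and 7 glycolysis genes in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231. Fatty acid oxidation had 2 of 19 lower in SK-BR-3 (0 to 2 without 1 library, ECI2 standing at -0.99, -0.93 and -0.98, not called, without SK-BR-3 DMSO 2, DMSO 3 or WA 5) and 0 by edgeR or DESeq2 in MCF-10A, MCF-7 and MDA-MB-231, with 6, 6 and 4 at an unadjusted p under 0.05 (0.519 to 0.869), or up to 1 call in MCF-7 without 1 library. Metallothioneins, Notch in the cancer lines, YAP and TEAD targets, basal markers in the cancer lines, fibroblast and leukocyte markers and the HER2 amplicon had adjusted p of 0.156 or more. So did the epithelial to mesenchymal list in the cancer lines (0.742 or more) and the tubulins there (0.263 or more). Without 1 library, the ribosomal list passed in MCF-7 (0.0173 without MCF-7 DMSO 3) and the fibroblast list in MCF-10A (0.0263 without MCF-7 DMSO 1 and 0.0267 without MDA-MB-231 WA 5), but not when the correlation was estimated in the same fits (0.883, 0.351 and 0.568). Of the 34 list tests that passed with an estimated correlation, 15 were lost without SK-BR-3 DMSO 1, WA 4 or WA 6, each left out alone, and 14 of these without SK-BR-3 WA 5. The other 19 were kept in every fit without 1 library. The cause was not tested. For lists where median, mean and direction of the test differed in sign, such as cholesterol synthesis in MCF-7 (median 0.29, mean -0.13) and apoptosis in SK-BR-3 (0.11 and -0.29), the test did not pass. With p-values adjusted over the list alone, the counts differed from those given by at most 3 genes in any list.

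Genes that responded in all 3 cancer lines show which changes these lines shared. With a single line per subtype and no contrast between cancer lines, dependence on subtype was not tested. The edgeR test called 272 genes with the same sign in the 3 cancer lines, 146 higher and 126 lower, where independent lists of these sizes would share 1.83 and 6.55. HMOX1, HSPA6, HSPA1A, OSGIN1, CHAC1, SESN2 and SQSTM1 were in this group. The numbers for independent lists took the call rates over all 18692 genes, with no allowance for expression level. They used the 2833 lower calls in MCF-7, of which 1279 were called again without MCF-7 DMSO 1. Without that library 343 genes were called with the same sign in the 3 cancer lines. Across all genes the responses of the lines correlated weakly, with Pearson's r of 0.203 to 0.241 and Spearman's rho of 0.231 to 0.398 for the 6 pairs of lines, genes not being independent replicates. The pair MCF-7 and SK-BR-3 shared 458 higher genes against 72.4 for independent lists, and 68 genes were called with opposite signs against 310.

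Of these, 70 genes were called with the same sign in MCF-10A too, 37 higher and 33 lower (0.0312 and 0.243 for independent lists). HMOX1 had the highest mean of the fitted log2 fold changes. The antioxidant gene OSGIN1 rose by log2 2.04, 3.73, 4.16 and 3.22 in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231, TXNRD1 by 1.43, 1.91, 2.73 and 2.12, and SQSTM1 by 1.80, 2.69, 2.66 and 2.10. HSP90AA1 rose by 1.25, 2.33, 1.98 and 1.62, and CHAC1 by 1.14, 5.19, 4.96 and 1.81. Among lower genes, OAS3 fell in each line (-1.83, -3.05, -1.83 and -1.69), as did CYP1A1 (-4.13, -3.01, -1.05 and -2.24). Further members, chosen after their values were seen, were the glutathione synthesis gene GCLM (2.06, 2.28, 3.42 and 2.77), TXNIP, an inhibitor of thioredoxin (-1.46, -3.73, -3.43 and -2.13), and IL8 (-3.24, -5.56, -5.45 and -1.05).

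Differences between the cancer lines and MCF-10A were tested as interactions. Among the cancer-selective genes, HSPA6, HSPA1A and GADD45A had the largest mean interactions. HSPA1A had a mean interaction of 4.30 (SE 0.18, adjusted p = 2.83e-14), with log2 responses of 3.99, 4.58 and 4.48 in MCF-7, SK-BR-3 and then MDA-MB-231 and 0.04 in MCF-10A. GADD45A (chromosome 1, 68150744 to 68154021) rose in the cancer lines (3.08, 2.12 and 1.46) and fell in MCF-10A (-1.93), a mean interaction of 4.15 (SE 0.22, adjusted p = 6.52e-12). It stood at 93.9 to 131 CPM in the MCF-10A DMSO libraries. After WA it stood at 72.9 to 108 CPM in MCF-7, 48.3 to 52.6 in SK-BR-3 and 109 to 124 in MDA-MB-231. Untreated MCF-10A was thus already at or above the treated level of the cancer lines. Whether this higher start shaped the difference was not tested. DDIT3 (chromosome 12, 57910371 to 57914300) had responses of 3.75, 2.57 and 1.94 against -0.39 in MCF-10A (mean interaction 3.14, SE 0.36). C1QTNF6 fell in the cancer lines (-1.40, -2.25 and -1.47) and rose in MCF-10A (1.56), a mean interaction of -3.26 (SE 0.22, adjusted p = 1.12e-10).

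**Figure D4:**
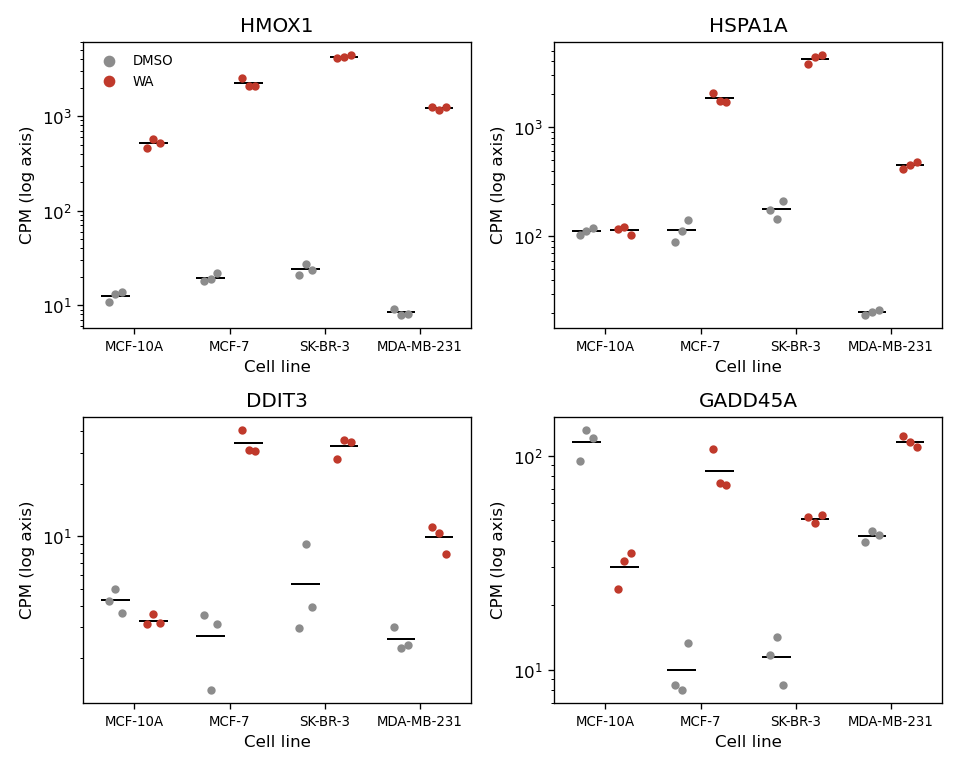
CPM of HMOX1, HSPA1A, DDIT3 and GADD45A on log axes, with 1 point per library and a line at the mean of the 3 libraries. HMOX1 rises in all 4 lines, HSPA1A and DDIT3 rise in the 3 cancer lines, and GADD45A rises in the cancer lines and falls in MCF-10A.

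The interaction with MCF-10A was called for 1885 genes in MCF-7 (887 higher, 998 lower), 2449 in SK-BR-3 (1361 and 1088) and 903 in MDA-MB-231 (582 and 321), and the mean interaction for 1196 (683 and 513). Without MCF-7 DMSO 1 the MCF-7 interaction had 1968 calls, 1240 higher and 728 lower. The cancer-selective response held 143 genes, 89 higher and 54 lower, of which 124 were not called in MCF-10A, 14 were called there with the same sign and 5 with the opposite sign. Its highest members by fitted value were HSPA6 (mean interaction 6.32, SE 0.40), HSPA1A, GADD45A, HSPA1B (3.51), SESN2 (3.31), the antisense gene AP001053.11 (3.21), the pseudogene RP11-443P15.2 and DDIT3. HSPA1A and HSPA1B are near-identical copies, and reads of the antisense gene and the pseudogene cannot be assigned with certainty without the strand and mapping settings, so the single values of these 4 genes are uncertain. Its lowest members by fitted value were EDN2 (-3.53, SE 1.01), C1QTNF6, NFATC4 (-3.07), MAN1C1 (-2.82), EFCAB4A (-2.73), ATOH8 (-2.51), MAP2K6 (-2.40) and MMP16. RP11-443P15.2 had 0 counts in SK-BR-3 DMSO and MMP16 in SK-BR-3 WA. With a floor of 3 counts there and the other lines as fitted, their mean interactions were 1.93 and -1.24. These values carry no margin for counting error, so their size and rank are uncertain. The mean interaction was not called without MCF-10A WA 5 or WA 6 for EDN2 (adjusted p up to 0.0824), nor without any 1 of 17 libraries for MAP2K6 (up to 0.177). Several of these were near the detection limit in MCF-10A, as EDN2 (0.12 and 0.14 CPM), NFATC4 (0.12 and 0.26) and MAN1C1 (0.14 and 0.32).

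Lists gave the same division. In the mean interaction, 15 of 25 heat shock genes were higher in the cancer lines (median 1.35, adjusted p = 2.5e-56), or 16 adjusted over the list alone. So were 16 of 25 integrated stress response genes with 1 lower (median 1.11, adjusted p = 2.55e-34), 8 of 27 NRF2 genes (0.61, adjusted p = 1.55e-10), 5 of 21 p53 targets (0.55, adjusted p = 5.58e-08) and 2 of 20 autophagy and lysosome genes (0.41, adjusted p = 1.01e-06). For the p53 targets part of this difference was a fall in MCF-10A, where 4 fell and 0 rose. In MCF-7 6 rose, while SK-BR-3 and MDA-MB-231 each had 2 higher and 1 lower. With an estimated correlation the heat shock, integrated stress and p53 lists passed without any 1 library, but NRF2 and autophagy did not without any 1 of 4 (up to 0.117 and 0.156). G2/M genes had 12 of 27 with a higher interaction (0.83, adjusted p = 1.26e-14), the median response being -1.59 in MCF-10A and -0.98, -0.48 and -0.28 in MCF-7, SK-BR-3 and then MDA-MB-231, a call lost with that estimate without any 1 of 5 libraries (up to 0.0945). The DNA replication list did not pass (4 of 30, adjusted p = 0.264). The calls of 5 other lists were lost with the second estimate: repair (5 of 22, 0.000899, and adjusted p = 0.0887 with an estimated correlation, or 0.0283 and 0.0364 with that estimate without MCF-7 DMSO 2 or WA 4), immediate early (6 higher and 1 lower, 6.97e-07, and adjusted p = 0.27 with an estimated correlation), Notch (3 higher and 2 lower, 0.00774, and adjusted p = 0.0521 with an estimated correlation, under 0.05 without any 1 of 14 libraries and 0.0144 at the lowest, with 3 to 5 higher and 1 to 2 lower without 1 library), cholesterol synthesis (0 of 24 by edgeR or DESeq2, 9 at an unadjusted p under 0.05, 0.0155, and adjusted p = 0.358 with an estimated correlation) and mitochondrially encoded genes (1 of 13 lower, median -0.72, 0.0139, and adjusted p = 0.762 with an estimated correlation, or 0.0553 without MCF-10A DMSO 1, with 0 to 5 lower without 1 library). The other lists had adjusted p of 0.0509 or more. Of these, apoptosis passed without any 1 of 17 libraries (0.0183 at the lowest, without MCF-10A DMSO 1), NF-kB targets without any 1 of 5 (0.0396, without MCF-10A DMSO 1), oxidative phosphorylation without any 1 of 3 (0.0227, without MCF-10A WA 4) and tubulins without any 1 of 3 (0.0136, without MCF-10A DMSO 1). None of these passed in the same fits with an estimated correlation (0.21 or more).

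WA-treated cancer lines were also compared with WA-treated MCF-10A, which asks how the lines differ under the drug. KRT19, a simple epithelial keratin, stood at 2082 ± 111 CPM in MCF-7, 7425 ± 167 CPM in SK-BR-3 and 321 ± 9.54 CPM in MDA-MB-231 and had 0 counts in WA-treated MCF-10A, at least 44866-fold, 160009-fold and 6912-fold higher against a floor of 3 counts in the 3 MCF-10A libraries. TFF1, an oestrogen-induced gene, was at 647 ± 57.9 CPM in MCF-7 with 0 counts in MCF-10A, and BCAS1 at 565 ± 21.6 CPM in SK-BR-3. In the other direction, GSTP1, a glutathione transferase, had 0 counts in MCF-7 and 923 ± 121 CPM in MCF-10A, at least 16616-fold lower. The edgeR test called 7898 genes for MCF-7 (4228 higher, 3670 lower), 9135 for SK-BR-3 (4513 and 4622) and 6555 for MDA-MB-231 (3144 and 3411).

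ATP2A3 and CACNA1H completed the highest in MCF-7, ATP2A3 and CTAG2 those in SK-BR-3, and BCAT1, SLC17A9 and HAS2 those in MDA-MB-231, each with 0 counts in MCF-10A. After GSTP1, the lowest in MCF-7 were KRT5 and KRT14, at 1 count each against 2534 ± 192 and 1961 ± 214 CPM, and CLCA2 with 0 counts. In SK-BR-3, HTRA1, DSG3, TMTC1 and TNFRSF10D had 0 counts. In MDA-MB-231, SLPI and S100A9 with 0 counts and KRT6A (0.18 ± 0.07 against 3658 ± 274 CPM, log2 -14.29) were among the lowest. The DMSO-treated lines differed to a similar extent, with 8652, 9926 and 6554 calls. Of the calls between WA-treated lines, 5934 (75.1%), 7169 (78.5%) and 5035 (76.8%) were also called in the same direction between the DMSO-treated lines. A called interaction was present for 1204 (15.2%), 1407 (15.4%) and 592 (9.03%) of the calls between WA-treated lines. A call absent between DMSO-treated lines was therefore not by itself a difference in response.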

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

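Tests chosen only after the result was seen were those on the lower depth of MCF-7 DMSO 1, on leaving out single DMSO libraries for the mitochondrial genes, on whether WA reached MCF-10A, on near-identical copies of heat shock genes, the regroupings of the list tests with an estimated correlation, and that estimate with each library left out. Each result here drew attention because the WA response of the 3 cancer lines differed from that of MCF-10A by a test of the interaction, apart from MCF-7 DMSO 1 and the mitochondrial genes, which stood out in the libraries themselves.

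Heat shock genes were higher after WA in the 3 cancer lines and not as a list in MCF-10A, with a median mean interaction of 1.35 over 25 genes (camera adjusted p = 2.5e-56, and adjusted p = 0.000148 with an estimated correlation). The data argued against 4 technical explanations, each only as far as its test reached. MCF-10A did not already stand at the treated level (median log2 of MCF-10A DMSO over the treated cancer lines -1.70, quartiles -2.24 and -1.01). WA was not absent from it, as 9 of 27 NRF2 genes rose there. A weaker effective exposure of MCF-10A stayed open, since that test excludes only an absence of WA. More NRF2 genes rose in the cancer lines (17 in MCF-7, 13 in SK-BR-3 and 15 in MDA-MB-231). G2/M genes went the other way, with 21 of 27 lower in MCF-10A against 13, 2 and 2. With DESeq2 size factors the median mean interaction of the heat shock list was also 1.35, against scaling. Of the 19 members without near-identical copies, 11 had a called higher interaction, against reads shared between copies. That cancer lines may induce these genes more readily than normal cells remains a hypothesis, because 1 line of normal origin stood against 3 cancer lines. Its normal origin cannot be told apart from its medium or growth state with 1 such line.

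Mitochondrially encoded transcripts were lower after WA in the 3 cancer lines, with list medians of -1.22, -1.83 and -0.97 in MCF-7, SK-BR-3 and then MDA-MB-231 and -0.53 in MCF-10A. The highest of the cancer medians was -0.96 under the other scalings, so the choice among these scalings did not account for it. The highest in MCF-7 or SK-BR-3 was -1.07 without 1 of their DMSO libraries, so no single such library did either. Leaving out 1 library cannot decide whether SK-BR-3 DMSO 1 and 3 did together, as the other stays in. They held 31.5% and 33.0% mitochondrial reads. SK-BR-3 DMSO 2 held 13.6%, close to the 10.7% to 12.9% of the SK-BR-3 WA libraries. Whether the list moved beyond the correlation among its genes stayed open (adjusted p of 0.728, 0.539 and 0.674 with an estimated correlation, but 0.0289 in SK-BR-3 without SK-BR-3 DMSO 2), as did whether MCF-10A shared the change, since the mean interaction had an adjusted p of 0.762 with that estimate. A lower mitochondrial RNA content after WA and a difference in RNA quality or dish handling are both possible and were not tested.

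MCF-7 DMSO 1 held reads over genes silent in the other MCF-7 libraries: of 4132 genes with 0 reads in the other 5, 3893 (94.2%) had a read in it, 48472 reads in all, against 8.30%, 9.01% and 18.5% in MCF-7 DMSO 2, DMSO 3 and WA 4, each over the genes with 0 reads in the 4 libraries left after also setting DMSO 1 aside. Its lower depth was excluded, as the deeper MCF-7 DMSO libraries had at most 21049 genes above 0, and reads carried over from the other lines were argued against by a Spearman rho of 0.118 with their FPKM across these genes, which are not independent replicates. The reads rose with gene length with a log-log slope of 0.92 (SE 0.0108), which is consistent with background spread evenly along gene models, such as genomic DNA. No biological explanation was tested.

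Other list medians of the mean interaction were 1.11 for the integrated stress response (adjusted p = 0.000605 with an estimated correlation), 0.83 for G2/M genes (0.0282), 0.61 for NRF2 genes (0.00935), 0.55 for p53 targets (0.00253) and 0.41 for autophagy and lysosome genes (0.0142). Without SK-BR-3 DMSO 1, WA 4, WA 5 or WA 6, each left out alone, the G2/M, NRF2 and autophagy lists did not pass with that estimate (adjusted p up to 0.0945, 0.117 and 0.156), nor did G2/M without MCF-7 DMSO 3 (0.0607).

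Among single genes, the mean interaction was 6.32 for HSPA6 (SE 0.40), with log2 responses of 6.82, 8.53 and 6.19 in MCF-7, SK-BR-3 and then MDA-MB-231 and 0.86 in MCF-10A. For HSPA1A it was 4.30 (SE 0.18) and for its near-identical copy HSPA1B 3.51 (SE 0.22), with MCF-10A at 0.04 and -0.08. GADD45A stood at 4.15 (SE 0.22), with -1.93 in MCF-10A. MCF-10A DMSO was already at 93.9 to 131 CPM of this gene, at or above the treated cancer lines. Whether that start shaped the difference was not tested. SESN2 stood at 3.31 (SE 0.15) and DDIT3 at 3.14 (SE 0.36), with MCF-10A at -0.46 and -0.39. The antisense gene AP001053.11 had 3.21 (SE 0.53), with responses of 1.38, 1.98 and 1.65 in the cancer lines and -1.54 in MCF-10A. The pseudogene RP11-443P15.2 had a fitted 3.18 (SE 0.84) that cannot be taken as a size, with 2.29 in MCF-10A, 3.18 in MCF-7 and 5.26 in MDA-MB-231. In SK-BR-3 it had 0 counts in DMSO and 1.76 CPM in WA, 18.6-fold higher against a floor of 3 counts over the 3 libraries. With that floor and the other lines as fitted its mean interaction was 1.93, without a margin for counting error.

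On the lower side, EDN2, the endothelin 2 gene, had a mean interaction of -3.53 (SE 1.01), with responses of -4.08, -3 and -2.94 in the cancer lines and 0.19 in MCF-10A, and was not called without MCF-10A WA 5 or WA 6 (adjusted p up to 0.0824). C1QTNF6 stood at -3.26 (SE 0.22), going from 73.4 to 27.9 CPM in MCF-7, 47.6 to 10.1 in SK-BR-3, 7.18 to 2.59 in MDA-MB-231 and 2.77 to 8.19 in MCF-10A. NFATC4 had -3.07 (SE 0.77), MAN1C1 -2.82 (SE 0.61), EFCAB4A -2.73 (SE 0.47) and ATOH8 -2.51 (SE 0.67), with MCF-10A at 1.08, 1.18, 1.23 and -0.18, none of them called there. MAP2K6 had -2.40 (SE 0.85), with -1.32 in MCF-10A, and was not called without any 1 of 17 libraries (adjusted p up to 0.177). MMP16 had a fitted -2.40 (SE 0.60), with -2.72 in MCF-7 and -1.09 in MDA-MB-231. In SK-BR-3 it had 0.196 CPM, a few reads, in DMSO and 0 counts in WA, 2.48-fold lower against the same floor. With the floor and the other lines as fitted its mean interaction was -1.24, without a margin for counting error.

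Other splits of the libraries were counted for each of these comparisons. The 10 splits of 3 libraries against 3 are too few for a share under 0.05. The real WA responses had 1010, 3730, 3210 and 948 calls in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231, the highest other splits 0, 3, 17 and 0, and 1 of the 10 splits, the real one, gave as many in each line. Between WA-treated lines the real values were 7898, 9135 and 6555 and the highest of the others 0 each, again 1 of 10 splits. For results of several lines, 31 joint regroupings of the labels within each line were counted, the real one included. At least as many calls came from 1 of 31 for the MCF-7 interaction (1885 against 1259 at most in the others), the MDA-MB-231 interaction (903 against 138), the mean interaction (1196 against 889), the genes called in 3 cancer lines (272 against 0), the cancer-selective response (143 against 0), the genes called in 4 lines (70 against 0) and the list tests with an estimated correlation (34 against 5). For the SK-BR-3 interaction it was 2 of 31 (2449 against 3301, in a regrouping that kept the MCF-10A labels and exchanged WA and DMSO in SK-BR-3, which adds the responses up), and for the list tests at the preset correlation 2 of 31 (67 against 70, with a median of 52). As WA changed each line, libraries exchanged within a line put its effect into the spread and into the contrasts, so these regroupings were no draws without an interaction and nothing was concluded on chance from any of them.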

How the results depend on the processing

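Tests chosen only after the data were seen were limma voom with library quality weights, the fit without mitochondrially encoded genes, and the estimated correlation with each library left out. Without 1 library, the calls ranged from 842 to 1476 in MCF-10A, 2619 to 4691 in MCF-7, 3007 to 3980 in SK-BR-3 and 784 to 1350 in MDA-MB-231. The ranges were 1483 to 2579, 2167 to 3000 and 785 to 1248 for the interactions of these cancer lines in the same order, 1029 to 1506 for the mean interaction, 249 to 343 for genes called in 3 cancer lines, 126 to 177 for the cancer-selective response, 65 to 92 for genes called in 4 lines, 7448 to 8662, 8633 to 9818 and 6179 to 7202 between WA-treated lines, and 67 to 73 for list tests that passed (67 with all libraries). Except in MCF-7 and its interaction, and for the list tests, each highest value was that without MCF-7 DMSO 1. Without it, the share of higher genes went from 24% to 51.7% in MCF-7 and from 47.1% to 63.0% in its interaction.

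With no fold threshold the calls were 3115 in MCF-10A, 7861 in MCF-7, 7426 in SK-BR-3 and 4099 in MDA-MB-231, 3825, 4927 and 2184 for the interactions, 3808 for the mean interaction, 1810 in 3 cancer lines, 1122 cancer-selective, 678 in 4 lines, and 11963 and 10683 for WA-treated MCF-7 and MDA-MB-231, by the construction of that setting. A fit of only the groups compared gave 2237 in MCF-7 (799 higher, 1438 lower) and 1455 for the MDA-MB-231 interaction, and voom with quality weights 2145 in MCF-10A, 2050 in MDA-MB-231, 2123 for its interaction and 2234 for the mean interaction, with 1393 higher and 1589 lower genes in MCF-7. As the groups shared 1 estimate of the spread, the calls of a line also depended on libraries outside its contrast. Without MCF-7 DMSO 1 they were 1476 in MCF-10A and 1350 in MDA-MB-231, against 1010 and 948. Voom gave that library the lowest weight (0.13). Numbers of calls therefore do not rank the lines by size of response. Other causes were not tested. With an estimated correlation 34 list tests passed with all libraries. Without 1 library there were 19 (SK-BR-3 DMSO 1 or WA 4), 20 (SK-BR-3 WA 5 or WA 6), 27 (MCF-7 DMSO 3), 39 (MCF-7 DMSO 1) and between 32 and 36 for the others (32, 33, 34, 35 or 36), and the cause was not tested. Every other count under DESeq2, its size factors, no low-count filter, the fit of only the groups compared, voom and the fit without mitochondrially encoded genes was within 1.5 times of that reported. DESeq2 called 1082, 3916, 3402 and 1000 genes in the 4 lines. The median log2 fold change of all genes in MCF-7 was -0.21, and -0.61 without the filter. Alternatives for normalized values (pseudocounts, an FPKM filter, quantile normalization) could not apply to counts and were not run.

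Of the genes called and named, 4 turned direction, each in MCF-7. CD19 stood at 0.047 with voom and PPP1R1B at 0.056. Without 1 library the fitted log2 fold changes ran from -7.17 to 1.86 for CD19, -7.01 to 1.86 for PPP1R1B, -9.05 to 1.87 for COL1A2 and -8.29 to 0.43 for PTPRC. Each highest value was that without MCF-7 DMSO 1 and was not called. Over all named genes and left-out libraries, 15817 values kept their side of the threshold, 211 lost the call and 72 gained it. DESeq2 ended 13 calls and added 7, its size factors 3 and 1, no filter 13 and 4, the fit of only the groups compared 6 and 5, and voom 12 and 17. Calls that many settings ended were those of CSF1R (24), MT-ND4 (16) and POLA1 (15) in MDA-MB-231, PSMC6 in SK-BR-3 (22) and the mean interaction of MAP2K6 (18).

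The library numbers, which the labels tie to no date or culture, were tested as a block between lines. Across 36 pairs with the same number the deviations from the group means correlated at -0.15 to 0.12 (median 0.00458, 1 over 0.1), across 72 with different numbers at -0.13 to 0.13, and 9 of 24 libraries correlated best with their own number. With the block the interactions had 1541, 2341 and 854 calls, the mean interaction 1108 and the cancer-selective response 139. The comparisons of WA-treated lines had 7747, 8924 and 6379. The 40 results of named genes in the mean interaction and between WA-treated lines kept their side of the threshold. The list tests were not run with the block. No paired analysis was possible because, for the responses within a line, DMSO libraries were numbered 1 to 3 and WA libraries 4 to 6, so they share no number.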

Other observations

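The tests here were planned, and only the genes marked as such were chosen after their values were seen. Metallothionein genes, whose proteins bind zinc and copper, were among those that fell in MCF-7 and SK-BR-3, in a list that did not pass in any line. MT2A fell from 46.1 ± 12.4 to 11.7 ± 0.82 CPM in MCF-7 and from 662 ± 110 to 254 ± 8.90 CPM in SK-BR-3 (edgeR log2 fold changes -1.98 and -1.38). MT1F fell by 2.13 and 2.51 on the log2 scale in the same lines. The gene of their zinc-sensing activator, MTF1, rose from 21 ± 2.05 to 46.6 ± 4.09 CPM in MCF-7, and in SK-BR-3 had a log2 fold change of 1.19, or 0.93, not called, without SK-BR-3 DMSO 2. Genes of adhesion and of YAP and TEAD were called in both directions. ITGA5, an integrin of the fibronectin receptor, rose from 10.7 ± 1.37 to 40.3 ± 6.30 CPM in MCF-7 and from 10.4 ± 1.28 to 85.0 ± 6.30 CPM in SK-BR-3. IGFBP3, a binding protein of insulin-like growth factors, fell in MCF-10A (85.8 ± 2.75 to 17.9 ± 2.56 CPM, log2 -2.26), MCF-7 (-2.84) and SK-BR-3 (-2.80) and stood at -0.72 in MDA-MB-231. CTGF fell in SK-BR-3 (-1.77), where the Hippo kinase gene LATS2 rose (1.48), and CYR61 rose in MCF-7 (1.24). NT5E, the gene of CD73, rose in MCF-10A from 68.3 ± 2.82 to 197 ± 6.93 CPM, and TGFB2 fell there (-1.87) and in MCF-7 (-1.64).

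Other calls concerned genes of lipid metabolism and of the cytoskeleton. ME1, the malic enzyme gene, rose in MCF-7 (68.4 ± 11.2 to 232 ± 13.3 CPM), SK-BR-3 (21 ± 3.65 to 85.8 ± 4.92) and MDA-MB-231 (17.5 ± 2.23 to 46.7 ± 0.71). In MCF-7 the stearoyl-CoA desaturase gene SCD rose from 563 ± 132 to 1343 ± 52.4 CPM and ACACB, an acetyl-CoA carboxylase gene, fell from 36.1 ± 6.18 to 6.74 ± 1.28 CPM. LSS, of cholesterol synthesis, fell in MCF-10A from 142 ± 6.01 to 66.3 ± 2.44 CPM. The citrate lyase gene ACLY stood at log2 fold changes of -0.48, -0.46, -0.42 and -0.19 in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231, and CPT1A, of fatty acid import into mitochondria, at 0.08, -0.13, -0.41 and 0.31, none of them called. STMN1, which destabilises microtubules, fell in MCF-7 from 127 ± 16.1 to 49.1 ± 5.33 CPM, and the gamma-tubulin gene TUBG1 fell in SK-BR-3 from 77.4 ± 8.96 to 28.7 ± 3.96 CPM. KRT6A, a stress keratin gene, rose in MCF-7 from 1.43 ± 0.73 to 20.3 ± 2.70 CPM and fell in MCF-10A (-1.05, but just under 1 in size, not called, without MCF-10A WA 6). Chosen after their values were seen, the proliferation gene E2F2 (-2.77, -1.45, -1.87 and -1.23), the mitotic kinase gene PBK (-2.61, -1.75, -1.33 and -1.18) and the replication gene HELLS (-1.42, -1.76, -1.71 and -1.41) fell in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231, while SRXN1, the sulfiredoxin gene (1.76, 3.03, 3.46 and 2.84), the taurine transporter gene SLC6A6 (1.81, 1.70, 2.00 and 1.55) and IKBKG, of the kinase complex upstream of NF-kB (1.54, 1.09, 1.87 and 1.11), rose.

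The authors' deposited table of each response held 4318, 4080, 6061 and 7552 genes at an adjusted p under 0.05 in MCF-10A, MCF-7, then SK-BR-3 and MDA-MB-231, of which 1106, 1764, 2777 and 1016 changed at least 2-fold. For the comparisons of WA-treated lines with MCF-10A, the authors' deposited table held 12516, 12736 and 11640 genes for MCF-7, SK-BR-3 and then MDA-MB-231, of which 8023, 9083 and 6674 differed at least 2-fold. Those sheets list only genes with a read in library 4 or 5 of the group named first.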
